A study of Mus musculus with 8 samples.

How the data were processed

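Total RNA from primary hepatocytes of male C57Bl/6 mice was measured on 8 single-channel Illumina bead arrays labelled with Cy3. 4 arrays held hepatocytes of mice fed normal chow (numbered 1, 2, 3 and 5 in the labels) and 4 those of mice fed a high fat diet (HFD, numbered 8, 10, 11 and 12). The series design text calls the arrays biological replicates. Whether each came from 1 mouse, how long the diets lasted and on which slide an array was run are not given in the sources used here. Per the labels' protocols, cells were plated in M199 medium with 10% serum, 100 nM insulin, 400 nM dexamethasone and 1.5 nM EGF. After 4 h the medium was changed to one with 10 nM insulin, and RNA was taken 24 h later. The RNA therefore came from cells cultured under shared hormone conditions, not from fresh liver.

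The file analysed was the authors' deposited table of log2 values, with 45281 probes and 8 columns, 1 column per sample. No column of sample values was left unused (0 columns). Per the submitters' processing notes the authors used lumi, a package for Illumina arrays; its version and steps are not given in the sources used here. The log2 unit was read from the values. Each column ran from 7.23 to 14.91 with a median of 7.51, and sorted values differed from the mean of the 8 arrays by at most 0.0026, so the columns already shared 1 distribution and were not normalized again. A shift of all genes on an array, or a difference in total RNA per cell, is removed by such a normalization. Whether the scale is a plain log2 or a variance-stabilised one is unknown, and detection p-values were not used here. Most probes lay near the floor of the scale, so a difference in a dim probe understates the change in RNA. A fold given below is 2 to the power of the log2 difference. For arrays, no count depth exists, and their number limits the precision.

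Probes were named from the platform annotation given with the value table and updated through a table of mouse genes of assembly GRCm38.p6, used for names only. A single symbol was found for 35784 probes, several symbols for 0, and none for 9497. Of the named probes, 28620 were matched by gene number, 2637 by transcript accession, 2128 by current symbol and 2343 by an older symbol, and 56 kept the annotation's own symbol. No genome build is given with the arrays, so no coordinates are reported. The named probes covered 20289 genes, of which 9180 had more than 1 probe. Each gene was represented by its probe with the highest mean over the 8 arrays. Probe ranges or means are given for the genes named by rule whose probes disagreed clearly.

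HFD was compared with chow in limma 3.58.1 under R 4.3.3, with lmFit and eBayes (no trend, 2-sided) over all 8 arrays and no covariate. Adjusted p-values are Benjamini-Hochberg values over the 20289 genes, or over all 45281 probes for the probe count, with a threshold of 0.05. For Fetub and Ahsg an exact 2-sided permutation test over the 70 assignments of the arrays was added; its smallest possible p is 0.0286. 31 gene lists were fixed before the data were examined: 23 pathway lists and 8 lists of markers of other cell types a hepatocyte preparation can hold. They name 631 memberships, of which 579 had a probe. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 31 lists, and again with an estimated correlation and with fry. The genes named in the text follow a rule fixed at the same time. They are Fetub and Ahsg; the 10 genes with the largest positive and the 10 with the largest negative difference among those past the threshold whose 4 HFD arrays all lay on 1 side of all chow arrays, passing over placeholder symbols; and, from each list, up to 3 members with the largest absolute difference among those past the threshold, or the 2 with the smallest p where none passed. A few other genes are named, and are said to be chosen after their values were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

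The tests were tested on simulated data with the real genes' means and spreads, for HFD against chow with 4 and 4 arrays and 20289 genes. The changed genes were drawn from those with a mean level above 8.5, so the shares recovered do not cover dimmer genes. Of genes changed by a log2 difference of 0.5, 43.3% were recovered, of those changed by 1, 79.1%, and of those changed by 2, 98.5%. Of 154 calls, 7 (4.55%) were of unchanged genes. All 3 of the random lists shifted by 0.5 were recovered and 0 of the others were called, with the preset and with the estimated correlation. The simulated genes varied independently of each other. The simulation therefore does not show how often correlated genes of a real list give a false call. For the same reason it does not show how well the test with an estimated correlation recovers a list of correlated genes. Every member of a shifted list moved by 0.5, so lists in which few members move were not covered. Alternatives tried were quantile normalization, centring each array on its median, filters to the brighter part of the probes (at a median or upper-quartile limit), eBayes with trend and robust settings, array weights, the mean of a gene's probes, a minimum log2 difference of 1, the 2 other list tests, and leaving out each array in turn. A fit for linear values was planned and not needed. The estimated correlation without the third chow array was added after the data had been seen.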

Results

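Primary hepatocytes were isolated from chow-fed and HFD-fed mice, cultured for about a day in the same medium, and profiled on 8 arrays, 4 per diet. The series title names Fetuin B as a secreted factor of steatotic hepatocytes, so the comparison asks how the hepatocyte transcriptome, and Fetub in particular, differed after the high fat diet. Levels below are the deposited log2 values as mean ± SD with n = 4 arrays per diet. Differences are HFD minus chow on the same scale, with their standard error (SE) and an adjusted p from limma. The arrays are called by diet and label number. The median level of all probes was 7.51, so values near 7.5 are close to background.

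Of 20289 genes, 820 (4.04%) differed between the diets, 299 higher and 521 lower in HFD hepatocytes. At an unadjusted p under 0.05 there were 2852. In all 820 the 4 HFD arrays lay on 1 side of the 4 chow arrays, which a call with 4 against 4 arrays nearly requires. Such separation was seen in 2173 genes (10.7%), against 2.86% by chance. Genes can vary together across arrays, so the share in 1 grouping can lie far from 2.86% by chance. A log2 difference of at least 1 was reached by 79 of the 820, 19 higher and 60 lower. Of all 45281 probes, 945 differed, 335 higher and 610 lower. The third chow array stood apart. It correlated with the other arrays at r = 0.946 to 0.952 across probes, whereas the other 7 arrays correlated at 0.989 or more. It carried the first principal component (59.8% of the variance), and the second (23.3%) separated the remaining chow arrays from the HFD arrays. On the second it lay at -6.10, nearer the HFD arrays (-8.49 to -10.0) than the other chow arrays (14.3 to 14.7). Without the third chow array 1861 genes differed, 981 higher and 880 lower, so the share of lower genes moved from 63.5% to 47.3%. All 820 genes were among the 1861 with the same sign. Leaving out an HFD array lowered the count by over 1.5 times, to 543 without HFD 8, 457 without HFD 10, 495 without HFD 11 and 447 without HFD 12, and without chow 2 the number of higher genes fell to 190. The count of probes moved likewise, to 579 without chow 1, 539 without chow 2, 2701 without chow 3, 517 without HFD 8, 433 without HFD 10, 469 without HFD 11 and 415 without HFD 12.

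**Figure D1:**
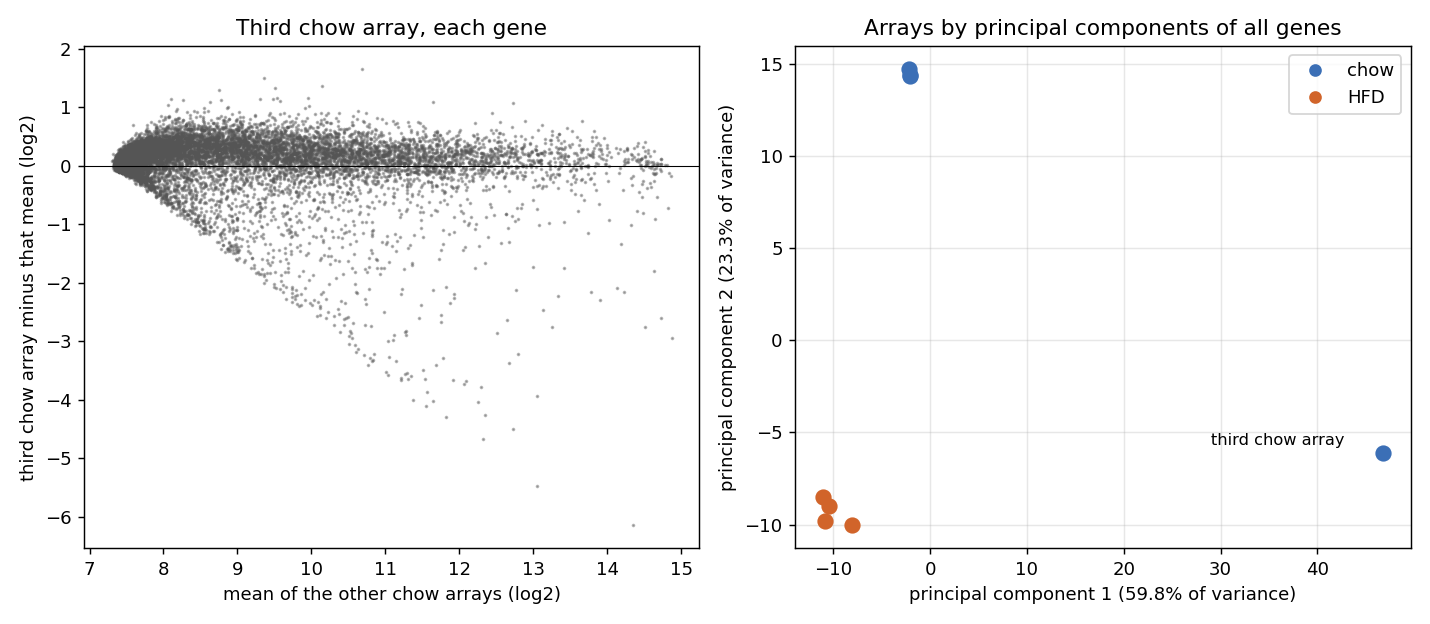
Left, the level of each gene on the third chow array minus its mean on the other chow arrays (log2, vertical) against that mean (log2, horizontal), 1 point per gene; right, the 8 arrays on the first and second principal components of all genes (59.8% and 23.3% of the variance), coloured by diet. Many genes fall far below 0 on the third chow array and few lie far above it. That array lies at 46.7 on the first component, away from the others, and at -6.10 on the second, nearer the HFD arrays.

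Fetub, which encodes Fetuin B, did not differ measurably between the diets. Its level was 11.26 ± 0.15 in chow and 11.22 ± 0.11 in HFD hepatocytes, a difference of -0.04 (SE 0.086, 95% confidence interval -0.24 to 0.16, adjusted p = 0.919; exact permutation p = 0.657). The sign turned without chow 5 (0.03) and without HFD 12 (0.001). These are RNA levels from 1 probe, and secreted Fetuin B protein was not measured on the arrays. Ahsg, which encodes the related Fetuin A, had a level of 12.98 ± 0.90 in chow and 14.49 ± 0.14 in HFD, higher in each HFD array than in any chow array. Its difference of 1.51 (SE 0.397) missed the threshold over all genes (adjusted p = 0.0929), while the exact permutation p was 0.0286, the smallest that 4 against 4 arrays can give. The spread came from the third chow array, where Ahsg read 11.67, 1.75 below the mean of the other chow arrays. Without that array the difference was 1.07 (adjusted p = 0.00107). With array weights it was 1.12 (adjusted p = 0.0106), and with the mean of both Ahsg probes 1.04 (adjusted p = 0.0241); over all alternatives its adjusted p ran from 0.00107 to 0.232. Its second probe gave a smaller difference of 0.57. The HFD level lay close to the highest value on the arrays, 14.91, where signals can be compressed.

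**Figure D2:**
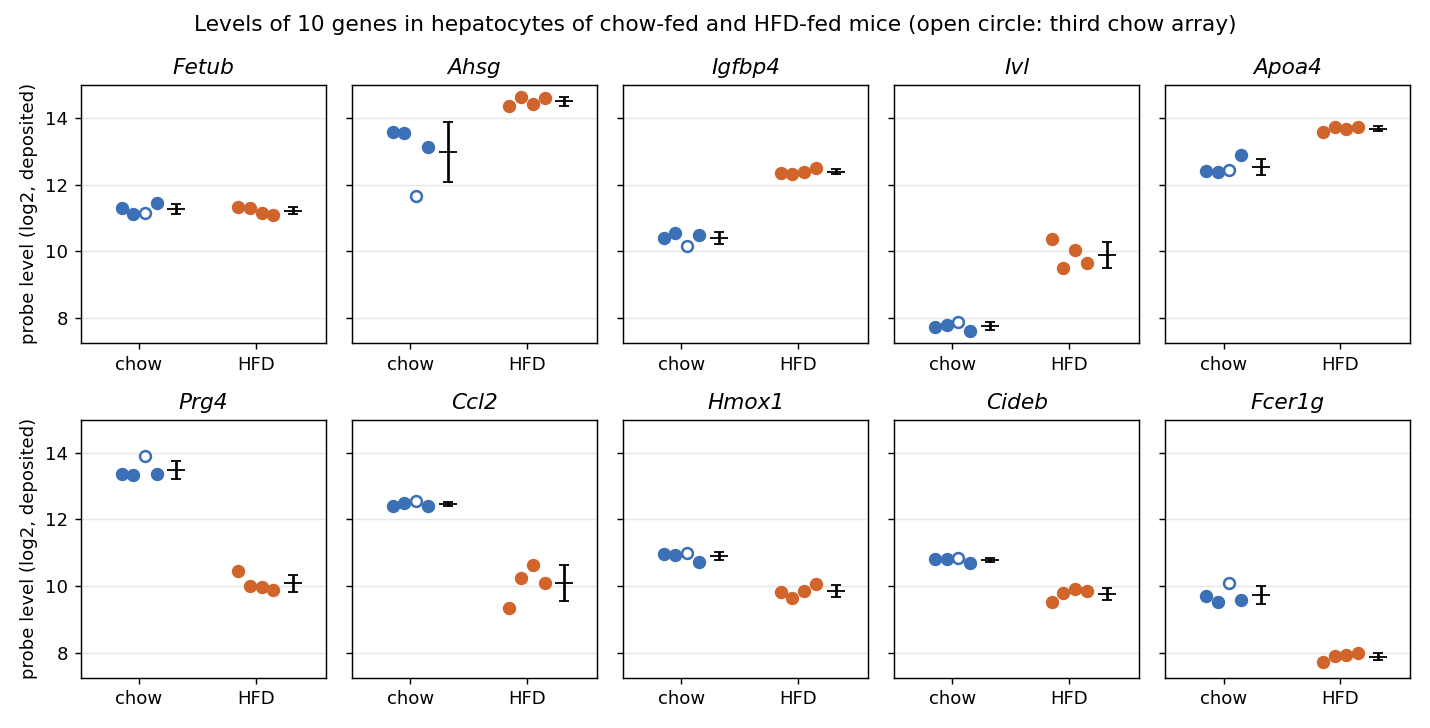
Deposited log2 level (vertical) of 10 genes in each array, by diet (horizontal); circles are arrays, the open circle is the third chow array, and the black bars give mean ± SD of the 4 arrays. Fetub overlaps between diets (11.26 and 11.22), Igfbp4, Ivl and Apoa4 lie higher in all HFD arrays, and Prg4, Ccl2, Hmox1, Cideb and Fcer1g lie lower in all of them.

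The genes that rose most in HFD hepatocytes included Ivl, Igfbp4 and Stbd1. Ivl, which encodes the cornified-envelope protein involucrin, rose from 7.75 ± 0.12, near background, to 9.88 ± 0.40, a difference of 2.13 (SE 0.182, adjusted p = 0.000868). Igfbp4, an insulin-like growth factor binding protein, rose from 10.39 ± 0.17 to 12.38 ± 0.08, by 1.99 or 3.98-fold (SE 0.085, adjusted p = 2.14e-05). Stbd1, a glycogen-binding protein, rose by 1.59 (adjusted p = 0.000929), Sprr1a, another cornified-envelope protein, by 1.45 (adjusted p = 0.000891), and the stress-induced regulator Nupr1 by 1.44 (adjusted p = 0.00424). Csn3, which encodes a casein, rose by 1.45, Etfbkmt, a methyltransferase of mitochondrial electron transfer flavoprotein, by 1.33, the integrin subunit gene Itga3 by 1.27, and Fam107b by 1.22. Erdr1 rose by 1.57 (SE 0.273, adjusted p = 0.0186) with a low value of 12.19 on HFD 8. Erdr1 lost its call without chow 1 or without HFD 10, 11 or 12 (adjusted p up to 0.0716). Probes of a gene disagreed in size for Ivl (0.61 to 2.13), Etfbkmt (0.56 to 1.33) and Csn3 (0.07 to 1.48).

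The genes that fell most in HFD hepatocytes included Prg4 and the chemokine genes Ccl5, Cxcl13, Ccl2 and Ccl7. Prg4, which encodes the secreted proteoglycan lubricin, fell from 13.48 ± 0.27 to 10.08 ± 0.26, a difference of -3.41 or 10.6-fold (SE 0.165, adjusted p = 4.48e-05). The chemokine genes Ccl5 (-2.60, SE 0.079, adjusted p = 4.29e-06) and Cxcl13 (-2.51, SE 0.058, adjusted p = 1.48e-06) fell to 7.60 and 7.63, close to background. Ccl2, which encodes a monocyte attractant, fell from 12.46 ± 0.07 to 10.08 ± 0.54, a difference of -2.38 (SE 0.236, adjusted p = 0.00163), and Ccl7 fell by 2.28 (adjusted p = 0.000669). Ms4a6d (-2.47), the formyl peptide receptor gene Fpr2 (-2.15), the non-classical major histocompatibility gene H2-M1 (-1.99), the growth factor binding protein gene Igfbp7 (-2.04) and the lysozyme gene Lyz1 (-1.91) fell as well, each with an adjusted p of 0.000593 or less. Lyz1 and the nearly identical Lyz2 can share probe signal, so this value is uncertain; the Lyz2 probe differed by -0.92 (adjusted p = 0.526), and by -1.49 without the third chow array (adjusted p = 0.00183). Prg4 probes ranged from -3.41 to -1.62, Ms4a6d probes from -2.47 to -1.45, Igfbp7 probes from -2.04 to 0.03 and Lyz1 probes from -1.91 to -0.01. Markers of macrophages were lower in the same HFD arrays, with a list median of -0.67.

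Of 21 measured macrophage and Kupffer cell markers, 10 fell and 0 rose in HFD cultures, and 15 fell both adjusted over the list alone and without the third chow array. The list shift had an adjusted p of 5.63e-14 by camera and an adjusted p = 0.250 with an estimated correlation. Fcer1g, an Fc receptor chain, fell from 9.73 ± 0.26 to 7.88 ± 0.11 (-1.84, SE 0.125, adjusted p = 0.000283), the lysosomal membrane protein gene Laptm5 fell by 1.46 (adjusted p = 0.000593), and Adgre1, a macrophage surface receptor gene, fell by 1.11 (adjusted p = 0.000319; its probes ranged from -1.11 to -0.11). Of 20 sinusoidal endothelial markers, 4 fell and 0 rose, and 9 fell adjusted over the list alone; without the third chow array 11 fell and 1 rose. Fcgr2b, an Fc receptor of these cells and of macrophages, fell by 1.37 (its probes ranged from -1.37 to 0.02), Lyve1 fell by 0.80 and Cdh5, the endothelial cadherin gene, fell by 0.78 (its probes ranged from -0.78 to -0.28). This list had a median of -0.25 and an adjusted p of 5.24e-07, or an adjusted p = 0.250 with an estimated correlation. Of 18 stellate cell and fibroblast markers, 2 fell, Sparc (-0.89, or -0.50 with the mean of its probes, which ranged from -0.89 to -0.27) and Bgn (-0.35), the same number adjusted over the list alone (list median -0.02, adjusted p = 0.0310, or an adjusted p = 0.481 with an estimated correlation). The stellate call was lost without chow 3, chow 5 or HFD 8, with an adjusted p of up to 0.0922, with array weights (0.0671), with the mean of a gene's probes (0.181) and when the dimmer probes were dropped at the upper quartile (0.156, median -0.27; -0.08 at the median limit). Its median was -0.04 without chow 1 or without HFD 12. Cdh5 lost its call without any array other than chow 1 or chow 3 (adjusted p up to 0.125), and Bgn without any other than chow 3 or chow 5 (up to 0.121). Of the 31 lists, 8 were called by camera, 2 higher and 6 lower in HFD, and 10 had an unadjusted p under 0.05. With an estimated correlation 0 lists were called with or without the third chow array (4 at an unadjusted p under 0.05 in both cases), and fry called 6.

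The other cell type lists showed no shift by camera. The median chow level of their members was 7.49 for lymphocytes, 7.50 for neutrophils and 7.53 for bile duct cells. It was 7.58 for red blood cells and 7.53 for adipocytes. All these medians lie near background, where a fall of a marker can hardly be seen. In the lymphocyte list 1 of 13 members fell, Ccl5, and in the neutrophil list 1 of 11, S100a8 (-1.07, SE 0.152, adjusted p = 0.00836), a calgranulin gene that macrophages can also express. Both counts were the same adjusted over the list alone, with adjusted p-values of 0.239 (0.00615 by fry) and 0.447 for the lists. Of 11 bile duct markers, 2 rose, Cldn4 by 0.58 and Tspan8 by 0.27 near background, also adjusted over the list alone (list adjusted p = 0.113). Of 7 red blood cell and 8 adipocyte markers none passed by limma, nor adjusted over the list alone, with 0 and 1 at an unadjusted p under 0.05 (list adjusted p = 0.777 and 0.615). The smallest p-values there belonged to Alas2 (-0.35, adjusted p = 0.601), Slc4a1 (0.04), Cidec (-0.22, adjusted p = 0.208) and Fabp4 (-0.06). Without the third chow array Cidec, a lipid droplet protein gene, passed (-0.27, adjusted p = 0.0471).

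Some inflammatory and interferon-related genes fell in HFD cultures, and both lists were called lower by camera but not with an estimated correlation (adjusted p = 0.529 for each). Of 22 NF-kB targets and chemokines, 5 fell and 0 rose (6 fell without the third chow array), led by Ccl2, Ccl7 and Cxcl1 (-0.58, SE 0.128, adjusted p = 0.0497), and 7 fell adjusted over the list alone. The list median was -0.11 (adjusted p = 0.000155, or an adjusted p = 0.529 with an estimated correlation and 0.0659 by fry). That median was -0.06 without chow 3, with array weights or with the mean of a gene's probes, -0.17 without HFD 11, and -0.21 with the dimmer probes dropped at the upper quartile. Of 22 interferon response and antigen presentation genes, 4 fell and 1 rose, also adjusted over the list alone (list median -0.08, adjusted p = 0.0275, or an adjusted p = 0.529 with an estimated correlation and 0.0659 by fry); without the third chow array 2 rose and 5 fell. The guanylate-binding protein genes Gbp2 (-1.20) and Gbp3 (-0.99) fell, as did Irf7 (-0.96), a transcription factor of the interferon response, while Irf1, named after its value was seen, rose by 0.46 (adjusted p = 0.0389). Irf1 lost its call without any array other than chow 3 or HFD 8 (adjusted p up to 0.124) and with the mean of its probes (0.16, adjusted p = 0.167). Gbp genes resemble each other closely and can share probe signal, and Gbp2 probes ranged from -1.20 to 0.01. In the same arrays the macrophage list median was -0.67. The interferon list lost its call without chow 1, chow 2, HFD 8 or HFD 12 (adjusted p up to 0.161; median -0.03 without HFD 8, and -0.13 without HFD 11) and when a gene was the mean of its probes (0.0662) or the dimmer probes were dropped (up to 0.127). Cxcl1 lost its call without any array other than chow 3 or chow 5 (up to 0.150) and, with its value from 1 probe unmoved, when other genes were the mean of their probes (0.0513), and Irf7 without any array other than chow 3 or chow 5 (up to 0.0912).

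Acute phase genes did not shift as a list. Of 24 measured members 1 rose and 1 fell, also adjusted over the list alone (list median 0.05, adjusted p = 0.394). Saa3, a serum amyloid gene of macrophages and stimulated hepatocytes, fell from 12.82 ± 0.21 to 11.19 ± 0.67 (-1.63, SE 0.308, adjusted p = 0.0265). Lcn2, which encodes lipocalin, rose by 0.18 (adjusted p = 0.0346) at 14.80 in HFD, close to the top of the scale. Saa3 read 10.19 on HFD 8, and the acute phase list passed camera at the preset correlation without that array (adjusted p = 0.0167), higher in HFD. With an estimated correlation and all 8 arrays the adjusted p of the list was 0.851. Saa3 lost its call without any array other than chow 3 or HFD 8 (adjusted p up to 0.0654) and with trend and robust settings (0.0609), and Lcn2 without any other than chow 3 or chow 5 (up to 0.113), with trend and robust settings (0.176), and when the dimmer probes were dropped (up to 0.139).

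Of 23 endoplasmic reticulum stress genes, 5 fell and 0 rose in HFD hepatocytes. The list median was -0.26 (adjusted p = 0.000909 by camera, or an adjusted p = 0.250 with an estimated correlation and 0.208 with that and without the third chow array). Of its members 8 fell and 1 rose adjusted over the list alone, as without the third chow array. Creld2, a secreted stress-response protein gene, fell from 11.64 ± 0.54 to 10.31 ± 0.11 (-1.32, SE 0.241, adjusted p = 0.0229), the disulfide isomerase gene Pdia4 fell by 0.87 (adjusted p = 0.000759) and Hspa5, which encodes the chaperone BiP, fell by 0.62 (adjusted p = 0.0299). Of 24 glutathione and antioxidant genes, 5 fell and 0 rose, and 5 fell and 2 rose adjusted over the list alone. Those that fell included sulfiredoxin gene Srxn1 (-1.08, SE 0.053, adjusted p = 4.64e-05; its probes ranged from -1.08 to -0.42), the heme oxygenase gene Hmox1 (-1.05, SE 0.098, adjusted p = 0.00123) and Slc7a11, the cystine transporter gene (-0.96, adjusted p = 0.000593; its probes ranged from -0.96 to -0.05). Gclm (-0.80) and Gclc (-0.42), subunits of the enzyme that limits glutathione synthesis, were named after their values were seen; Gclm lost its call without HFD 8, 10 or 11 (adjusted p up to 0.0593) and Gclc without any array other than chow 3 or chow 5 (up to 0.149). The antioxidant list did not pass by camera (median -0.07, adjusted p = 0.271, or an adjusted p = 0.529 with an estimated correlation) but did by fry (adjusted p = 0.000760), and without the third chow array 1 rose. Of 21 immediate early and heat shock genes 3 fell, Hsph1 (-0.79), Ier3 (-0.69) and Klf6 (-0.29, with a second probe at -0.08), 4 fell without the third chow array, and 5 fell and 2 rose adjusted over the list alone. By camera this list had an adjusted p of 0.0854, or 0.0162 without chow 1 and 0.0337 without HFD 10. With an estimated correlation and all 8 arrays it was 0.851. Creld2 lost its call without chow 2 or any HFD array (adjusted p up to 0.0840), Hspa5 without any array other than chow 3 or chow 5 (up to 0.0966), Ier3 without HFD 11 (0.0587), and Klf6 without chow 1, chow 5 or HFD 10, 11 or 12 (up to 0.0933) and with the mean of its probes (0.600). Macrophage markers, with a list median of -0.67, were lower in the same arrays.

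Lipid metabolism genes changed in few members. Several members lay near background in both diets, where a fall cannot be seen and a rise is understated. Examples, named after their values were seen, are Fasn (7.52 in chow, 7.45 in HFD), Cd36 (7.44 and 7.44) and Cpt1a (7.47 and 7.42). Of 22 fatty acid and triglyceride synthesis genes, 3 rose and 1 fell, and 5 rose and 2 fell both adjusted over the list alone and without the third chow array. Me1, malic enzyme, rose from 9.66 ± 0.16 to 10.43 ± 0.15 (0.76, SE 0.097, adjusted p = 0.00500), the acetyl-CoA synthetase gene Acss2 by 0.55 (adjusted p = 0.00935; its probes ranged from 0.04 to 0.55) and the desaturase gene Scd1, named after its value was seen, by 0.47 (adjusted p = 0.00766). Mlxipl, which encodes the glucose-responsive factor ChREBP, fell by 0.67 (adjusted p = 0.00192). The list median was 0.12 (adjusted p = 0.00902, or an adjusted p = 0.250 with an estimated correlation and 0.0659 by fry), and the call was lost without the third chow array (adjusted p = 0.186, median 0.06), with array weights (0.0957) and when the dimmer probes were dropped at the upper quartile (0.127). The median was 0.05 with the mean of a gene's probes. Of 20 lipid droplet genes 1 fell, Cideb (-1.01, SE 0.087, adjusted p = 0.000891), a droplet protein of hepatocytes; the count was the same adjusted over the list alone, and without the third chow array 2 rose and 2 fell. Of 22 fatty acid oxidation genes 2 fell, Acot1 (-0.36) and the medium-chain dehydrogenase gene Acadm (-0.34), and 1 rose and 2 fell both adjusted over the list alone and without the third chow array. Of 16 lipoprotein genes Apoa4 rose by 1.16 (SE 0.111, adjusted p = 0.00137; its probes ranged from 1.16 to 1.75) and Apoc1 fell by 0.29, also adjusted over the list alone, and without the third chow array 2 rose. None of 18 cholesterol synthesis and uptake genes passed by limma, nor adjusted over the list alone, with 3 at an unadjusted p under 0.05; Dhcr7 differed by -0.59 (adjusted p = 0.207) and Srebf2 by 0.27 (adjusted p = 0.231), or by -0.10 with the mean of its probes (0.27 and -0.46). The adjusted p of these other lists was 0.932 for lipid droplets, 0.407 for oxidation, 0.777 for lipoproteins and 0.473 for cholesterol. For lipid droplets the median (0.002) and the mean (-0.002) differ in sign and the test pointed down, and for lipoproteins the median was -0.01, the mean 0.12 and the test pointed up. Acot1 probes ranged from -0.36 to 0.05. Acot1 lost its call without HFD 10, 11 or 12 (adjusted p up to 0.0566) and with the mean of its probes (0.109), Acadm without HFD 11 or 12 (up to 0.0689), and Apoc1 without any array other than chow 3 or chow 5 (up to 0.116), with the mean of its probes (0.187) and when the dimmer probes were dropped at the upper quartile (0.0517).

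**Figure D3:**
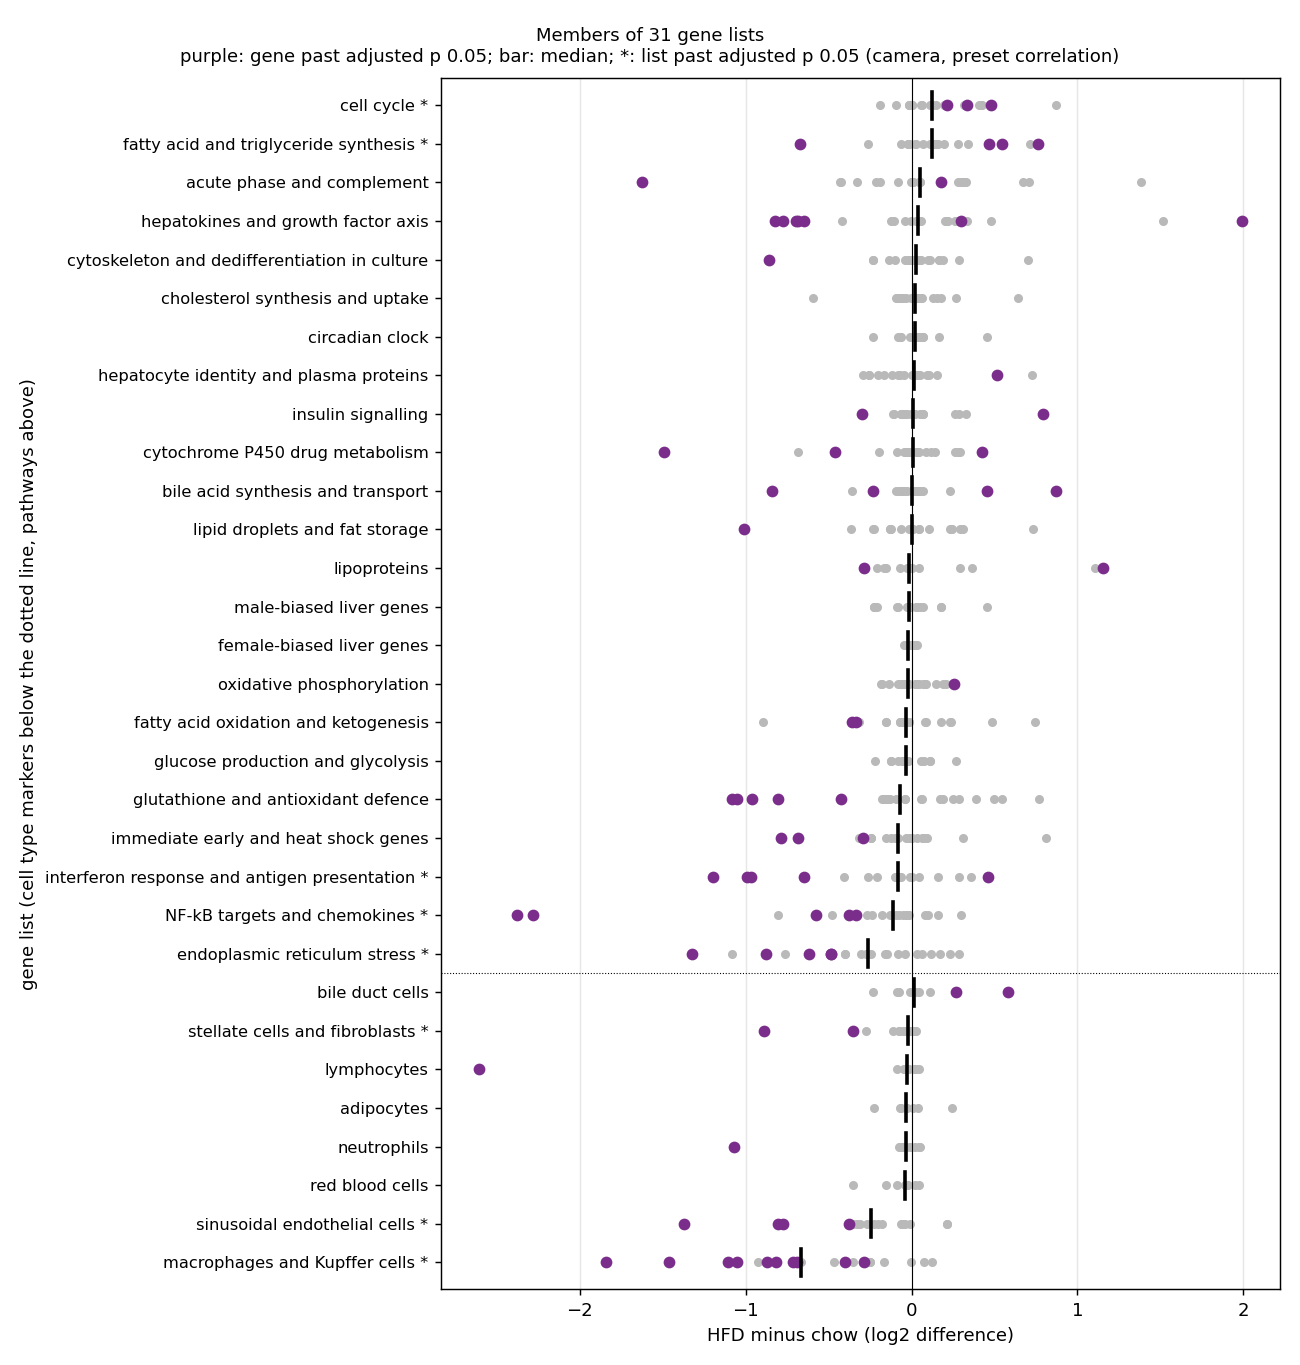
HFD minus chow log2 difference (horizontal) of each measured member of 31 gene lists (vertical), pathways above and cell type markers below the dotted line; purple points are genes past an adjusted p of 0.05, grey points are not, black bars are list medians, and asterisks mark the lists called by camera with the preset correlation. The macrophage list has the lowest median, -0.67, and most medians lie close to 0.

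Secreted factors moved in both directions. Of 24 measured hepatokine and growth factor genes, 2 rose and 5 fell, and 8 rose and 7 fell adjusted over the list alone; without the third chow array 9 rose and 5 fell. Beside the rise of Igfbp4, Hamp, which encodes hepcidin, fell by 0.82 (SE 0.110, adjusted p = 0.00634) and Igfbp2 fell by 0.78 (SE 0.040, adjusted p = 6.82e-05; its second probe gave -0.34). The list as a whole had a median of 0.04 (adjusted p = 0.654). Of 20 insulin signalling genes 1 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.473). Grb10, an adaptor that restrains insulin receptor signalling, rose by 0.79 (SE 0.126, adjusted p = 0.0131; its probes ranged from 0.002 to 0.79), and the kinase gene Gsk3b fell by 0.30 (adjusted p = 0.0420). None of 14 glucose production and glycolysis genes passed by limma, nor adjusted over the list alone, with 4 at an unadjusted p under 0.05 (list adjusted p = 0.932; median -0.04 and mean -0.01, with the camera test pointing up), with Pdk2 at 0.11 (adjusted p = 0.302) and Ldha at -0.22 (adjusted p = 0.312). The median level of these 14 glucose genes was 7.82 in chow and 7.79 in HFD, close to background. A fall of a dim member could hardly be seen there, and a rise is understated. The other genes of the 20 listed had no named probe. The glucose transporter gene Slc2a2, named after its value was seen, differed by 0.27 (adjusted p = 0.351). Slc2a2 passed without the third chow array (0.37, adjusted p = 0.0139), with array weights (0.36, adjusted p = 0.0257) and with the mean of its probes (0.17, adjusted p = 0.0269). Grb10 lost its call without HFD 10 (adjusted p = 0.0518), Gsk3b without any array other than chow 1 or chow 3 (up to 0.122), with trend and robust settings (0.140) and when the dimmer probes were dropped at the upper quartile (0.0519), and Igfbp2 with the mean of its probes (0.158).

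Bile acid and drug metabolism genes did not move as lists. The bile acid list was dim, with a median level of 7.85 in chow and 8.17 in HFD, so a fall of its dimmer members could hardly be seen. Of 21 bile acid genes 2 rose and 2 fell, and 2 rose and 3 fell adjusted over the list alone (adjusted p = 0.648); without the third chow array 4 rose. The phospholipid exporter gene Abcb4 rose by 0.87 (SE 0.112, adjusted p = 0.00540) and the uptake transporter gene Slco1b2 by 0.45 (adjusted p = 0.00988; its probes ranged from 0.02 to 0.45). Nr1h4, which encodes the bile acid receptor FXR, fell by 0.84 (SE 0.089, adjusted p = 0.00205). Of 20 cytochrome P450 genes and regulators 1 rose and 2 fell, and 3 rose and 2 fell adjusted over the list alone (adjusted p = 0.777; the median, 0.01, and the mean, -0.07, differ in sign, and the test pointed up). Cyp2f2 fell by 1.49 (SE 0.230, adjusted p = 0.0114) and Cyp2b10 fell by 0.46 (adjusted p = 0.0255; its probes ranged from -0.46 to 0.02), and the xenobiotic receptor gene Nr1i2 rose by 0.43 (adjusted p = 0.0206). Members of the P450 family are similar in sequence, and their probes can share signal. Without the third chow array 2 of the list rose and 3 fell. Cyp2b10 lost its call without chow 2 or HFD 10, 11 or 12 (adjusted p up to 0.0827) and Nr1i2 without chow 1, chow 2 or HFD 8, 10 or 12 (up to 0.0761).

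Hepatocyte identity, respiratory chain, sex-biased and clock genes showed few or no changes. The female-biased list had a median level of 7.47 in chow and 7.46 in HFD, near background, so a fall there could hardly be seen. The clock list was dim too, at 7.79 and 7.86. Of 20 hepatocyte identity and plasma protein genes 1 rose, the urea cycle gene Cps1 (0.51, SE 0.078, adjusted p = 0.0105), and of 26 oxidative phosphorylation genes 1 rose, Cyc1 (0.26, adjusted p = 0.0255). Both counts were the same adjusted over the list alone, and the lists had adjusted p-values of 0.777 and 0.815. Without the third chow array 2 oxidative phosphorylation genes rose. None of 16 male-biased, 15 female-biased or 16 circadian clock genes passed by limma, nor adjusted over the list alone, with 2, 0 and 3 at an unadjusted p under 0.05 (list adjusted p = 0.615, 0.777 and 0.777). The male-biased list had a median of -0.01 and a test pointing up, and the oxidative phosphorylation list a median of -0.02, a mean of 0.004 and a test pointing up. The genes with the smallest p were Nudt7 (0.18, adjusted p = 0.0869; its probes ranged from -0.03 to 0.18) and Cyp7b1 (0.46, adjusted p = 0.234), Hao2 (-0.04) and Cyp3a44 (0.04), and Bhlhe40 (0.45, adjusted p = 0.0963) and Arntl (-0.23, adjusted p = 0.279). Without the third chow array Nudt7, Cyp7b1 and Bhlhe40 passed (adjusted p = 0.0484, 0.0280 and 0.0489), as they did with array weights (0.0434, 0.0403 and 0.0212). Bhlhe40 also passed without chow 5 (adjusted p = 0.0283) and with trend and robust settings (0.0347). Cyc1 lost its call without any array other than chow 3 or HFD 11 (adjusted p up to 0.0884), with trend and robust settings (0.0945) and when the dimmer probes were dropped at the upper quartile (0.0574).

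Of 23 measured cell cycle genes 3 rose and 0 fell in HFD hepatocytes, 4 rose adjusted over the list alone, and 5 rose without the third chow array. The list median was 0.12 with 18 of 23 members higher (adjusted p = 0.000155 by camera, or an adjusted p = 0.529 with an estimated correlation and 0.183 by fry). That median was 0.22 without chow 3, 0.07 without chow 5, and 0.27 with the dimmer probes dropped at the upper quartile. Tyms, thymidylate synthase, rose from 9.10 ± 0.20 to 9.58 ± 0.09 (0.48, SE 0.098, adjusted p = 0.0359), the topoisomerase gene Top2a from 7.60 to 7.93 near background (0.33, adjusted p = 0.00482), and Ccne1, which encodes cyclin E, by 0.21 (adjusted p = 0.0323). Of 21 genes of the cytoskeleton and of dedifferentiation in culture 1 fell, the thymosin gene Tmsb4x (-0.86, SE 0.178, adjusted p = 0.0381), which blood cells also express strongly; the count was the same adjusted over the list alone (list adjusted p = 0.777). Tyms lost its call without any array other than chow 2 or chow 3 (adjusted p up to 0.116), Ccne1 without chow 2, chow 5 or HFD 8, 10 or 11 (up to 0.102), with trend and robust settings (0.297) and when the dimmer probes were dropped at the upper quartile (0.0905), Top2a with the mean of its probes (0.0891), and Tmsb4x without any array other than chow 3 or HFD 11 (up to 0.125) and with the mean of its probes (0.0580). Probes of Tyms ranged from 0.005 to 0.48, of Top2a from 0.02 to 0.33, and of Tmsb4x from -0.86 to -0.01.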

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

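The tests of the third chow array, of the cell type markers and of the normalization were chosen after the results they bear on had been seen, while the counts over other groupings of the arrays were planned.

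The third chow array stood far from the others of its diet, with a mean correlation of 0.951 with them against 0.981 for the rest. Of 6598 bright probes (mean level of at least 9), 785 (11.9%) lay at least 1 below the other chow arrays on it and 17 more than 1 above. Loss of the transcripts themselves as the main cause is argued against by other bright probes of the same genes, which deviated by 0.0699 of the low probes' amount (95% bootstrap interval 0.0055 to 0.138, 436 low probes in 343 genes). The low probes were picked for lying low, which makes this ratio smaller. A ratio of medians also leaves open a loss of transcripts in a part of the genes. Independent failure of single probes at 1 shared rate is argued against by the 33.7% of such other probes that were low too (27.3 to 39.6). Among all bright probes of genes with more than 1, 16.9% were low. Probes were not matched for level here, so independent failure at rates that differ by level or gene stays open. A wrong diet label is argued against by the array's position over 418 genes, 0.0478 (-0.0095 to 0.148). On that scale 0 is the other chow arrays and 1 the HFD arrays. Its value of -6.10 on the second principal component, taken over all genes, lay nearer the HFD arrays. A fault shared by groups of probes stays open, and no biological explanation other than a loss of transcripts was tested.

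Of the macrophage and sinusoidal endothelial markers, 10 of 21 and 4 of 20 were lower in HFD cultures past the threshold. Fewer macrophages carried over may account for the macrophage part, but this stays open: 10 of 10 macrophage markers with a chow mean of at least 8.5 were lower (median -0.90), which restates the pattern, the brightest being Slc11a1 (11.47 to 10.66), Cd14 (11.21 to 10.53; hepatocytes also express it) and Cd68 (10.49 to 9.43). A like loss of all other liver cells cannot be told apart either. Between chow means of 8.5 and 10 the 5 endothelial and stellate markers had a mean of -0.58, against -1.03 for 7 macrophage markers (exact 2-sided permutation p = 0.205 over genes). The 5 were Fcgr2b (-1.37), Sparc (-0.89), Lyve1 (-0.80), Egfl7 (-0.06) and Stab1 (0.22). By the same permutation test the p was 0.0128 once brighter markers of both sets were added. Among these were Ecm1 (11.57 to 11.60), Cldn4 (11.49 to 12.07) and Sox9 (10.59 to 10.35), whose high baseline can hide a small share. Both p-values take markers as independent, though all come from the same 8 arrays, so they do not measure the spread between cultures. Fcgr2b, the lowest of the 5, is a receptor of macrophages too. Lower NF-kB activity cannot be told apart: the 8 members of that list with a chow mean of at least 8 that are not chemokines or cytokines had a median of -0.0599 (-0.24 to 0.07), but they leave out called members, and all 10 members with a chow mean of at least 8.5 had a median of -0.37 with a wide interval (-1.43 to -0.02). The macrophage, endothelial and stellate lists share 0 members with other lists, and an effect of the diet on these cells or on their number in the liver stays open and untested.

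With the third chow array 63.5% of the differing genes were lower in HFD, and without it 47.3%. A candidate explanation, which stays open, is that normalization to 1 shared distribution lifted the remaining bright probes of that array: the median deviation of all bright probes from the other chow arrays was 0.114 on it, against -0.011 to -0.00035 on the others. Of 35 groupings of the 8 arrays into 4 and 4, only the real one (1 of 35) gave as many as 820 genes, where the highest other gave 1. The same held for probes (1 of 35; 945 against 0), and for lists (1 of 35; 8 against 7, from the grouping that exchanges chow 5 and HFD 8). Without the third chow array 1 of 35 groupings gave as many as 1861 genes, the highest other giving 1. The real grouping thus ranked first for genes and probes, which is the best rank that 35 groupings allow. Each other grouping mixes the diets, so a diet difference widens its spread and lowers its count. The size of the gap therefore does not exclude chance. For lists the margin was 1 and an estimated correlation called 0. A batch that follows the diets is not excluded by these counts, as the slide of each array is not given in the sources used here.

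Single arrays also stood apart from the others of their diet in the levels of named genes and in list means. Of 236 groups examined 29 met the rule, where chance gives about 1 in 20, or 11.8. Of these 29, 13 were on HFD 8. The groups are not independent, since they share arrays and genes. Of the 86 named genes, 70 had passed the fit with all 8 arrays, which a large deviation on 1 array hinders. The flags therefore do not rank the arrays. HFD 8 had a mean correlation of 0.996 with its diet and an array weight of 1.18, against 0.951 and 0.192 for the third chow array. On HFD 8, Erdr1 was 12.19 (others 13.31), Ms4a6d 7.67 (7.83), Lyz1 8.79 (9.45), Cyp2f2 8.38 (9.10), Saa3 10.19 (11.53), Top2a 7.83 (7.96) and Cidec 7.82 (7.74). List means on HFD 8 were 9.25 for fatty acid oxidation (9.23), 11.34 for lipoproteins (11.50), 8.82 for glucose production (8.91), 8.93 for cytochrome P450 genes (9.16), 10.67 for acute phase genes (11.13) and 8.71 for male-biased genes (8.96). On chow 5, Itga3 was 11.37 (10.82), Ms4a6d 9.63 (10.47), Apoa4 12.87 (12.40), Lyve1 8.21 (8.68) and the cytochrome P450 mean 8.98 (9.23). On chow 3, Prg4 was 13.89 (13.35), Cyp2b10 9.92 (9.63), the insulin signalling mean 9.02 (8.84) and the female-biased mean 7.46 (7.48). On chow 1, Gsk3b was 9.02 (9.23) and Cps1 8.18 (8.47). On HFD 11 the bile acid mean was 8.86 (8.80) and the red blood cell mean 7.63 (7.59), and on HFD 12 Nudt7 was 11.14 (11.01) and Cyp3a44 7.36 (7.46).

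Among the 9497 probes without a gene name, which the gene comparison did not use, 86 differed between the diets, 39 higher and 47 lower in HFD.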

How the results depend on the processing

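The estimated correlation without the third chow array was chosen after seeing the data; the other alternatives were planned. Of the 820 genes, 819 were called after quantile normalization and 818 after median centring. The columns already shared 1 distribution, so these settings could change little. They are no check of the normalization, also where they enter the counts of named genes below. With the dimmer probes dropped 900 were called at the median limit (807 shared) and 717 at the upper quartile (623 shared), with trend and robust settings 814 (658 shared), and with the mean of probes 767 (629 shared). Apart from the arrays left out, named genes other than Fetub and Ahsg kept their direction and side of the threshold in 549 of their values, lost the call in 18, gained it in 4 and turned in 1, Srebf2 (-0.10 with the mean of its probes). With 1 array left out, 560 values of these genes were unmoved, 107 lost and 5 gained the call; fewer arrays give less precision. The causes of the other changes were not tested. Signal over background limits dim probes, whose differences are understated.

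Array weights gave 1603 genes (771 higher, 832 lower), 1894 probes (842 higher, 1052 lower), 1 higher list and an Ahsg difference of 1.12. A log2 difference of at least 1 left 79 genes (19 higher, 60 lower) and 96 probes (25 higher, 71 lower). At the upper quartile 5 lists were called, 1 of them higher. Camera with an estimated correlation called 0 lists (0 higher, 0 lower), also without the third chow array, and fry called 0 higher lists. The mean of its probes gave Ahsg 1.04. Leaving out 1 array gave 447 to 1861 genes (157 to 981 higher, 290 to 880 lower), 415 to 2701 probes (135 to 1349 higher, 280 to 1352 lower), 6 to 9 lists (1 to 3 higher, 4 to 7 lower), and differences of -0.087 to 0.025 for Fetub and 1.07 to 1.71 for Ahsg.

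In lists that were not called, the direction of the test turned in some settings while the medians stayed close to 0. The medians there were 0.0022 for lipid droplets and -0.035 for glucose production with trend and robust settings; -0.019 for lipoproteins and 0.0082 for cytochrome P450 genes with array weights; 0.025 for adipocytes with the dimmer probes dropped at the median limit; and -0.035 for glucose production, 0.0075 for cytochrome P450 genes and 0.038 for hepatokines by fry. With an estimated correlation and without the third chow array they were 0.0011 for lipoproteins and -0.0050 for cytoskeleton genes. Leaving out 1 array, the medians ran from -0.0066 to 0.019 for lipid droplets (turned without chow 2 or chow 5), from -0.069 to 0.018 for lipoproteins (chow 3, chow 5), from -0.045 to 0.014 for glucose production (chow 2, HFD 10), from -0.020 to 0.035 for cytochrome P450 genes (chow 5), from -0.032 to 0.035 for hepatocyte identity (chow 5, HFD 11), from -0.029 to 0.018 for oxidative phosphorylation (chow 1, chow 5, HFD 8), from -0.0050 to 0.032 for cytoskeleton genes (chow 3) and from -0.068 to -0.015 for red blood cells (chow 5). Over all alternatives the adjusted p of the called lists ran from 1.01e-17 to 0.250 for macrophages, 7.17e-09 to 0.250 for endothelial cells, 2.85e-05 to 0.250 for endoplasmic reticulum stress, 1.77e-05 to 0.613 for NF-kB targets, 1.06e-06 to 0.529 for cell cycle, 0.00157 to 0.619 for fatty acid synthesis, 0.00478 to 0.613 for interferon response and 0.0159 to 0.481 for stellate cells. A larger pseudocount, planned for linear values, was not run, because the values were already log2. No paired analysis was possible because the chow and HFD arrays share no replicate number.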

Other observations

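The genes in this part were picked after their values had been seen, mostly as examples from the 820 that differed. Those that were lower included genes for secreted factors, some of which endothelial cells also express; the endothelial marker list had a median of -0.25 in the same arrays, with Lyve1 at -0.80 and Cdh5 at -0.78. Esm1, which encodes the proteoglycan endocan, fell from 10.63 ± 0.08 to 8.78 ± 0.04 (-1.84, adjusted p = 1.48e-06 from limma, n = 4 arrays per diet), Angpt2, an angiopoietin gene, differed by -1.76 (adjusted p = 7.04e-06; its probes ranged from -1.76 to -0.14) and the endothelin gene Edn1 by -1.19 (adjusted p = 3.52e-05). Npy, which encodes neuropeptide Y, differed by -1.84 (adjusted p = 0.000106), and Bmp4, a bone morphogenetic protein gene, by -1.79 with a second probe at -0.06. Erfe, which encodes erythroferrone, a suppressor of hepcidin, differed by -1.76 with a second probe at 0.01, beside the lower Hamp. Creb3l3, a liver transcription factor gene, fell from 10.13 ± 0.35 to 8.43 ± 0.09 (-1.69, adjusted p = 0.00126), while Apoa4 and Fgf21, which it is known to induce, differed by 1.16 and 0.21 (adjusted p = 0.00137 and 0.255). Fgf21 passed without the third chow array (0.26, adjusted p = 0.0404) and with array weights (0.26, adjusted p = 0.0446). Cyba, a subunit gene of the phagocyte oxidase, fell from 9.12 ± 0.05 to 7.95 ± 0.05 (-1.17, adjusted p = 4.57e-06), beside a macrophage list median of -0.67.

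Some hepatocyte genes were among those that were higher, while Cyp2f2 (-1.49), Nr1h4 (-0.84), Mlxipl (-0.67) and Acadm (-0.34) were lower and the hepatocyte identity list had 1 of 20 members higher (list adjusted p = 0.777). Itih2, which encodes a plasma protease inhibitor chain, rose from 10.99 ± 0.24 to 12.17 ± 0.07 (1.19, adjusted p = 0.00122). Gulo, for vitamin C synthesis, rose by 1.00 (adjusted p = 0.00334), the alanine aminotransferase gene Gpt by 0.89 (adjusted p = 0.00426) and the fatty acid transporter gene Slc27a2 by 0.76 (adjusted p = 0.00356). The tight junction gene Cldn2 rose by 1.18 (adjusted p = 0.000462) and the gap junction gene Gjb2 by 0.96 (adjusted p = 0.00587; its probes ranged from 0.46 to 0.96). No enrichment of these groups was tested.

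Plin2, which encodes a lipid droplet coat protein, illustrates the effect of the third chow array on a single gene. Its level was 12.06 ± 1.97 in chow and 12.80 ± 0.14 in HFD (0.73, adjusted p = 0.816), with 9.10 on the third chow array, a deviation of -3.94 from the other chow arrays. Without that array the difference was -0.25 (adjusted p = 0.0684), and with array weights -0.06 (adjusted p = 0.962).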
